A study of Homo sapiens with 6 samples.

How the data were processed

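RNA was measured in HEK293T cells, an established line derived from human embryonic kidney that carries the SV40 large T antigen. Cells were kept for 24 h with 20 mM oxamate, a pyruvate analogue that inhibits lactate dehydrogenase, or without it. The samples without it are labelled PBS, the buffer. Each group had 3 libraries, and per the labels' protocols total RNA was turned into libraries with a NEBNext Ultra RNA kit for Illumina sequencing. By its name this is the version of the kit that does not keep the strand. The labels did not say whether the 3 samples of a group were separate cultures, so every p-value measures the spread between these samples, which may be technical.

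The deposited table gave 1 FPKM value (fragments scaled to gene length and library total) per gene and library, made by the authors. Beside these it gave the authors' own comparison as a log2 fold change, an average log2 count per M, a p-value and a false discovery rate, per the file headers. The genome build was hg38, per the submitters' processing notes. The aligner and counter used for these RNA libraries, the annotation and the filter on genes are not given in the sources used here. The submitters' processing notes also list FastQC 0.11.9, Bowtie2 2.4.4, MACS3 3.0.0b1 and ChIPseeker 1.34.1 without a role. The authors' log2 fold change equalled the log2 ratio of the mean FPKM of the groups, with an SD of the difference of 0.00343 over genes, so both carried the same scaling. The lowest average in the table was 0.85 counts per M, so genes with few reads had been removed before deposit. The table was read as 14206 rows. In 21 rows the gene name had been turned into a date by spreadsheet software, and these rows were kept in the fit but not named. No values of the 13 mitochondrially encoded protein genes were in the rows used here.

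Gene names were matched to the RefSeq table of GRCh38.p14. Of the identifiers, 13124 equalled a current symbol, 844 matched 1 gene through an older symbol, and 217 matched none. Coordinates of named genes and of the genes overlapping them are from the GENCODE annotation of GRCh38, the assembly that hg38 names. Positions and gene counts used for the major histocompatibility complex region, and for genes compared with it, are from the RefSeq table. GC content and length were taken from each gene's longest annotated transcript, and 97.8% of the tested genes had a GC value.

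The depth behind the values was estimated from the steps between low values, since a gene's FPKM is a whole number of fragments times a constant. The library totals that best made the low values whole were 12.3 M for PBS-1, 12.8 M for PBS-2, 12.3 M for PBS-3, 11.3 M for oxamate-1, 10.4 M for oxamate-2 and 11.8 M for oxamate-3. Between 53.8% and 73.8% of the low values then lay within 0.15 of a whole read. Values with no steps give 30% at a total fixed beforehand, and more where, as here, the total is chosen on the same values. These totals are therefore approximate, and so are the comparisons below that use them. In the shallowest library a gene of median length at 1 FPKM had about 34.7 fragments, a counting error of 16.98%, and one at 10 FPKM had an error of 5.37%. These errors cover counting only, and a shorter gene at the same FPKM has fewer fragments and a larger error. The fold change of a gene near 1 FPKM is therefore less precise than that of an abundant gene. A gene's FPKM also depends on how fragments shared between copies of a gene, or between overlapping genes, were counted, and the strand setting of the counting is not given in the sources used here.

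Before averaging, libraries were compared against sampling noise with a chi-square statistic per gene over genes with 40 to 200 fragments in a pair. Its mean was 1.45 for oxamate-1 against oxamate-3 and between 3.26 and 5.89 for the other 14 pairs, where sampling noise alone gives about 1. The values of oxamate-1 and oxamate-3 were not identical and differed by more than sampling noise, so the libraries were kept as separate samples. The labels do not say whether these libraries came from 1 culture. If they did, the group would hold fewer independent samples than its n states and the p-values would be too small. A fit with both averaged into 1 library was added as an alternative, and it called 0 genes.

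The groups were compared with limma 3.58.1 in R 4.3.3 on log2(FPKM + 1), with a variance trend on mean expression, for the 12582 genes with a mean of at least 1 FPKM over the 6 libraries. The test was two-sided with Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(FPKM + 1) scale, which understates the change of low genes, and errors of fold changes are standard errors from limma. Of 52 gene lists fixed before the data were examined, the 47 with at least 5 tested members were compared with all other genes with camera at a preset correlation of 0.01, again with Benjamini-Hochberg adjustment. Camera with an estimated correlation and fry, which tests whether a list moves on balance one way without comparing it with other genes, were run beside it. For each list the number of members past the threshold was also taken with p-values adjusted over the list alone. The test, the lists, most alternatives and the rule for named genes were set before the data were examined.

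Named genes were all measured members of the list of lactate, pyruvate and acylation enzymes, up to 10 called genes per direction with the largest change at a mean of at least 5 FPKM and no overlap of the groups, and the 5 genes with the smallest p-value in each direction. In each called list the up to 4 members with the smallest p-values in the list's direction were taken, and 1 called member against it, of which there was none. Genes named outside this rule are said to have been chosen after their values were seen.

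Values were simulated with the real genes' means and spreads, and 200 of the 12582 genes were changed. The limma fit called 22% of genes changed by 0.5 on the log2 scale, 84% of those changed by 1, 98% of those changed by 2 and 100% of those changed by 4. Among the unchanged genes there were 7 false calls. The simulated noise was independent between genes, unlike that of real libraries. The alternatives covered pseudocounts, filters, scalings, the variance model, the replicate number as a block, each library left out, thresholds, and, added after the data were seen, a correction for GC content per library, a covariate for the mean of the interferon list, protein-coding genes alone by RefSeq type, and an adjusted p under 0.10. The GC correction subtracted, per library, the lowess trend (span 0.3) of the deviation from the gene mean on GC content. Tables and figures were made with Python 3.11.15, pandas 2.3.3, NumPy 2.4.6, SciPy 1.17.1 and matplotlib 3.10.9.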

Results

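The transcriptome of HEK293T cells was compared after 24 h with 20 mM oxamate and with PBS, with 3 libraries in each group. The study's title concerns lysine pyruvylation, an acylation of proteins written by the acetyltransferases HAT1 and p300 and removed by the deacylase SIRT3, and its link to glycolysis. The comparison asked which transcripts differ when lactate dehydrogenase, the enzyme that interconverts pyruvate and lactate, is inhibited. The library totals estimated from the values ranged from 10.4 M fragments in oxamate-2 to 12.8 M in PBS-2. Between 12434 and 12591 genes had at least 1 FPKM in a library. The labels do not say whether the libraries came from separate cultures, so the p-values measure the spread between these samples only.

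Transcripts of a neuronal membrane protein, a glycosyltransferase and a p53-inducible membrane protein were lower with oxamate, and 1 small nucleolar RNA was higher. LINGO1, a leucine-rich repeat protein of the neuronal surface, fell from 13.05 ± 0.2999 FPKM (SD, n = 3) with PBS to 5.39 ± 0.202 FPKM (SD, n = 3) with oxamate, 2.42-fold lower. GYLTL1B, now named LARGE2, which extends the sugar chains of dystroglycan, fell from 17.7 ± 1.22 to 8.19 ± 0.627 FPKM. TP53I11 fell from 21.2 ± 1.33 to 10.7 ± 0.676 FPKM. SNORA72, a box H/ACA small nucleolar RNA, rose from 3.57 ± 0.545 to 9.73 ± 0.832 FPKM. In each of these 4 genes all 3 oxamate libraries lay on one side of all 3 PBS libraries.

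These were the 1 higher and 3 lower genes among 12582 tested with limma at a Benjamini-Hochberg adjusted p under 0.05. The log2 fold changes were -1.14 ± 0.09 (SE) for LINGO1 with an adjusted p of 0.0202, -1.03 ± 0.10 for GYLTL1B with 0.0374, -0.93 ± 0.10 for TP53I11 with 0.0390 and 1.23 ± 0.12 for SNORA72 with 0.0374, all from limma. LINGO1 lies on chromosome 15 from 77613027 to 77820900 on the minus strand, with annotated antisense RNAs inside it. GYLTL1B lies on chromosome 11 from 45921621 to 45929096 on the plus strand. TP53I11 lies on the same chromosome from 44885903 to 44951306 on the minus strand, and its span overlaps TSPAN18 on the plus strand. TSPAN18, chosen after its values were seen, was at 7.16 ± 0.732 FPKM with PBS and 3.87 ± 0.0479 FPKM with oxamate (adjusted p = 0.0602 in limma), so fragments of the overlapping pair cannot be assigned to one strand here. SNORA72 lies on chromosome 8 from 98042086 to 98042217 on the minus strand, in an intron of RPL30, and is uncertain because fragments of the host transcript or of an overlapping antisense RNA can be counted in it. It is also far shorter than the median implied gene length of 3335 bases, so its FPKM rests on far fewer fragments than that of a median gene. The authors' false discovery rate for SNORA72 was 0.0609. RPL30 itself was between 514 and 897 FPKM with PBS and between 726 and 842 FPKM with oxamate.

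The threshold fell just before a large group of genes that shared 1 adjusted p. A further 236 genes had an adjusted p of 0.0602 in limma, 326 genes were higher and 606 lower at an adjusted p under 0.10, and 2782 had an unadjusted p under 0.05 against 629 given by chance. In 3607 genes, or 28.7%, the 2 groups did not overlap, where chance gives 10%. Splits of the libraries into 3 and 3 that mixed the groups had 43 to 1435 genes at an unadjusted p under 0.05 in limma. Genes are not independent of each other, so neither excess over chance counts the genes that respond to oxamate. Leaving out PBS-1, PBS-3, oxamate-1, oxamate-2 or oxamate-3 left 0 calls in limma in each case, with 1685 to 2980 genes at an unadjusted p under 0.05, and leaving out PBS-2 gave 827 higher and 1273 lower genes, with all 4 genes above among them. On GC content, deviations of genes from their mean over the 6 libraries had a slope above 0 in PBS-1 and PBS-3. The slope was below 0 in each oxamate library. The counts of the fit without PBS-2 therefore cannot be told apart from a GC bias between libraries.

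Among the other genes with the smallest p-values, all at an adjusted p of 0.0602, the lower ones were PPDPF at 54.5 ± 1.24 FPKM with oxamate against 98.3 ± 9.39 FPKM with PBS, and GDF7, a growth factor of the BMP family, at 0.820 ± 0.261 against 2.77 ± 0.274 FPKM. The higher ones included GTF3C6, a subunit of the RNA polymerase III factor TFIIIC, at 106 ± 2.396 FPKM with oxamate against 65.5 ± 4.60 FPKM with PBS. CCDC150 was at 11.04 ± 0.0796 against 6.67 ± 0.415 FPKM. MIR548AN, which lies within an intron of CXorf57, was at 15.7 ± 1.41 against 7.97 ± 0.927 FPKM and cannot be told from its host. THUMPD3-AS1 was at 17.5 ± 0.603 against 9.50 ± 1.27 FPKM and overlaps exons of THUMPD3 on the other strand, so its value is uncertain too.

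**Figure D1:**
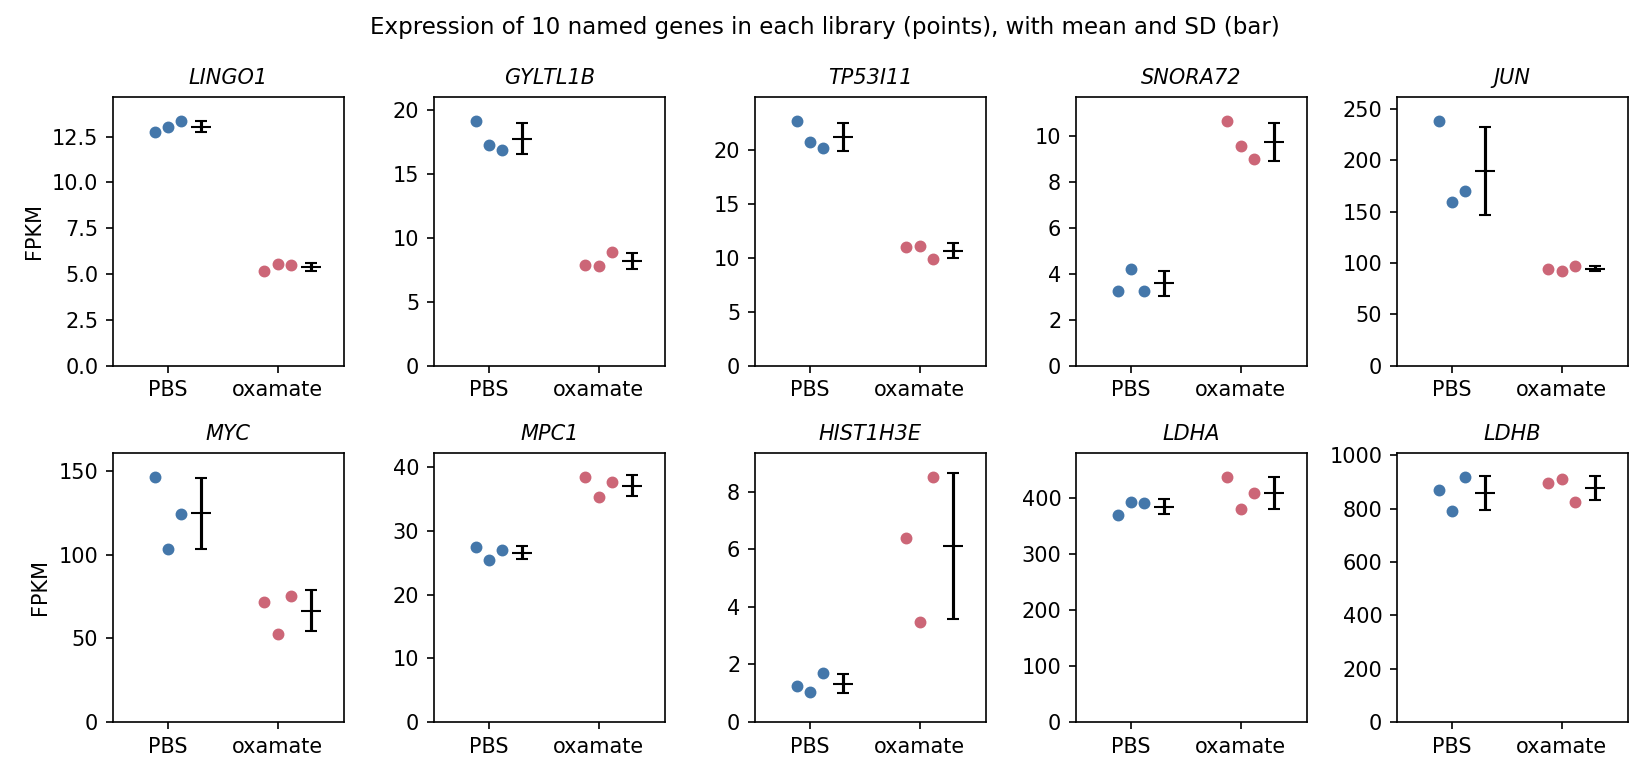
FPKM (vertical axes, from 0) of 10 named genes in the 3 PBS libraries (blue points) and the 3 oxamate libraries (red points), with group mean and SD as a black bar. LINGO1 lies at 13.05 FPKM with PBS and 5.39 FPKM with oxamate with no overlap, while LDHA and LDHB overlap between the groups.

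LDHA and LDHB, the lactate dehydrogenase subunits with the most transcript in these cells, were at similar levels in both groups, and no lactate dehydrogenase gene passed the test. LDHA was at 384 ± 13.6 FPKM with PBS and 408 ± 28.1 FPKM with oxamate (log2 fold change 0.09 ± 0.10, SE, adjusted p = 0.654 in limma). LDHB was at 859 ± 63.8 and 878 ± 46.7 FPKM (0.03 ± 0.12, adjusted p = 0.902). LDHC was at 4.15 ± 0.513 and 5.88 ± 0.596 FPKM with no overlap of the groups (log2 fold change 0.42 ± 0.12, adjusted p = 0.102) and LDHD at 1.84 ± 0.509 and 1.88 ± 0.297 FPKM. The pyruvate kinase PKM was at 629 ± 97.0 and 622 ± 32.7 FPKM.

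The acylation enzymes, taken into a list from the study's title before the files were seen, did not pass the test singly. HAT1 was at 68.3 ± 5.67 FPKM with PBS and 84.9 ± 4.82 FPKM with oxamate, 1.24 times as high with no overlap of the groups (adjusted p = 0.124 in limma). EP300, which encodes p300, was at 21.3 ± 3.62 and 22.6 ± 1.74 FPKM, and its paralogue CREBBP at 17.2 ± 2.34 and 18.6 ± 1.55 FPKM. The deacylase SIRT3 was at 11.9 ± 1.97 and 11.1 ± 0.858 FPKM (log2 fold change -0.08 ± 0.13, SE). KAT2A was at 61.5 ± 11.2 and 65.4 ± 9.84 FPKM, and KAT2B at 4.44 ± 0.945 and 5.25 ± 0.252 FPKM.

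MPC1, a subunit of the carrier that brings pyruvate into mitochondria, was at 26.6 ± 1.06 FPKM with PBS and 37.1 ± 1.63 FPKM with oxamate (log2 fold change 0.47 ± 0.08, SE, adjusted p = 0.0602 in limma). It was the 1 member of 19 in the enzyme list to pass when adjusted over the list alone (limma adjusted p = 0.0123), against 0 over all genes tested. MPC2 was at 20.1 ± 2.08 and 22.2 ± 1.51 FPKM. Of the pyruvate dehydrogenase complex, DLD was at 37.7 ± 2.95 and 46.7 ± 1.86 FPKM, PDHB at 95.2 ± 13.3 and 116 ± 3.12 FPKM, DLAT at 25.8 ± 2.07 and 30.2 ± 1.52 FPKM, PDHX at 17.4 ± 1.06 and 19.1 ± 0.157 FPKM and PDHA1 at 58.4 ± 7.16 and 59.1 ± 1.88 FPKM. The pyruvate carboxylase PC was at 9.65 ± 2.60 and 9.76 ± 0.670 FPKM. As a list these enzymes were higher, with 17 of 19 fold changes above 0 and a median of 0.11 (camera adjusted p = 0.01003; adjusted p = 0.623 with an estimated correlation). The list lost its call without PBS-2 (adjusted p = 0.0648).

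Of the 47 lists tested, 5 were higher and 9 were lower with camera at its preset correlation. None of these 14 calls held with an estimated correlation or with fry, whose adjusted p-values for these lists ran from 0.0577 to 0.529. Splits of the libraries into 3 and 3 that mixed the groups also called lists at the preset correlation, from 6 to 16 each. Fry's mixed test, which asks whether members change in either direction, passed for 28 lists. No member of a called list passed over all genes tested. Adjusted over the list alone, 1 or more members passed in 10 of the 14.

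The lists of nuclear oxidative phosphorylation genes and of mitochondrial ribosomal proteins were higher. Of 58 nuclear genes of oxidative phosphorylation, 51 had a fold change above 0, with a median of 0.20 and 0 members past the test adjusted over the list alone (camera adjusted p = 0.000858; adjusted p = 0.815 with an estimated correlation). NDUFC2, of complex I, was at 5.01 ± 0.877 FPKM with PBS and 8.11 ± 0.302 FPKM with oxamate. CYCS, cytochrome c, was at 39.1 ± 5.41 and 52.3 ± 3.09 FPKM, NDUFV2 at 60.9 ± 5.59 and 75.1 ± 0.881 FPKM, and UQCRB of complex III at 26.2 ± 4.68 and 35.0 ± 0.942 FPKM. Of 44 mitochondrial ribosomal proteins, 32 had a fold change above 0, with a median of 0.15 (camera adjusted p = 0.00924; adjusted p = 0.690 with an estimated correlation). MRPL47 was at 23.9 ± 2.26 and 32.7 ± 2.25 FPKM, MRPL15 at 41.4 ± 2.23 and 53.2 ± 2.61 FPKM, MRPS14 at 22.7 ± 0.761 and 28.8 ± 1.18 FPKM, and MRPL1 at 12.7 ± 1.91 and 17.8 ± 1.45 FPKM. The oxidative phosphorylation list had its lowest mean in PBS-2, at 6.24 on the log2 scale, against 6.75 to 6.92 in the other 5 libraries. Without PBS-2 its adjusted p was 0.827 and that of the mitochondrial ribosome list 0.275. Only in PBS-2 did deviations of genes from their mean rise with transcript length, with a rho of 0.434 across genes. This rho was negative in the other 5 libraries. The ribosomal protein list was also lowest in PBS-2, at 8.78 against 9.23 to 9.46. No correction for length was run, so the calls of both mitochondrial lists cannot be told apart from a length bias of PBS-2.

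Transcripts of replication-dependent histones were higher by the largest median of any called list, 0.81 over 10 tested members, of which 7 passed adjusted over the list alone (camera adjusted p = 0.000510; adjusted p = 0.623 with an estimated correlation). HIST1H3E was at 1.33 ± 0.338 FPKM with PBS and 6.13 ± 2.54 FPKM with oxamate, HIST1H2BD at 3.06 ± 1.42 and 10.2 ± 3.36 FPKM, HIST1H1C at 6.16 ± 2.28 and 16.3 ± 4.49 FPKM, and HIST1H2AC at 3.29 ± 1.16 and 7.58 ± 2.30 FPKM. The list mean was 2.13 in PBS-1, 1.98 in PBS-2, 2.58 in PBS-3, 3.25 in oxamate-1, 2.59 in oxamate-2 and 3.38 in oxamate-3, so oxamate-2 lay level with PBS-3. The list was fixed as a sign of RNA quality, since most such messages carry no poly(A) tail, and 10 of its 50 genes were among the rows used here. Other RNAs that lack a poly(A) tail gave a median of 0.09 over 7 tested genes (camera adjusted p = 0.431).

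Targets of p53 were higher as a list, with 22 of 24 fold changes above 0, a median of 0.34 and 0 members past the test adjusted over the list alone (camera adjusted p = 0.00568; adjusted p = 0.743 with an estimated correlation). TP53I3 was at 3.00 ± 1.48 FPKM with PBS and 6.97 ± 0.920 FPKM with oxamate, RPS27L at 16.4 ± 7.06 and 38.8 ± 11.5 FPKM, RRM2B at 6.13 ± 0.656 and 9.09 ± 1.59 FPKM, and TIGAR at 4.47 ± 0.302 and 6.71 ± 1.62 FPKM. HEK293T cells carry the large T antigen, which binds p53. The list mean was 3.43 in PBS-1, 3.29 in PBS-2, 3.81 in PBS-3, 4.08 in oxamate-1, 3.39 in oxamate-2 and 4.09 in oxamate-3, so oxamate-2 lay among the PBS libraries. The mean of the interferon list went the other way, at 5.09, 4.48, 1.78, 1.82, 4.37 and 1.81 in the same order. The p53 list lost its call without PBS-2 (adjusted p = 0.106), without oxamate-3 (0.0512) and with the interferon list mean as a covariate (0.123).

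Immediate-early genes, which serum and stress switch on within minutes, were lower. Of 19 tested members 16 had a fold change below 0, 6 passed adjusted over the list alone, and the median was -0.30 (camera adjusted p = 0.00168; adjusted p = 0.623 with an estimated correlation). JUN was at 189 ± 42.6 FPKM with PBS and 94.5 ± 2.46 FPKM with oxamate, with a log2 fold change of -0.97 ± 0.15 (SE). JUND was at 49.6 ± 9.49 and 29.3 ± 2.75 FPKM, NR4A1 at 10.5 ± 2.87 and 5.12 ± 1.54 FPKM, and JUNB at 25.7 ± 15.4 and 8.93 ± 2.46 FPKM. The list mean was 4.14 in PBS-1, 3.78 in PBS-2, 3.58 in PBS-3, 3.33 in oxamate-1, 3.46 in oxamate-2 and 3.40 in oxamate-3. Each PBS library thus lay above each oxamate library, with PBS-1 the highest.

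Genes of the extracellular matrix and of epithelial-mesenchymal transition were lower, with 18 of 23 fold changes below 0, 7 past the test adjusted over the list alone and a median of -0.34 (camera adjusted p = 0.000719; adjusted p = 0.623 with an estimated correlation). The fibronectin receptor subunit ITGA5 was at 25.7 ± 2.74 FPKM with PBS and 15.8 ± 1.25 FPKM with oxamate, the collagen COL6A2 at 25.3 ± 5.97 and 12.6 ± 1.22 FPKM, and the matrix protein SPARC at 45.3 ± 3.43 and 34.3 ± 1.23 FPKM. CDH1, the epithelial cadherin that this transition lowers, was at 2.05 ± 0.224 and 0.998 ± 0.139 FPKM, so its direction was that of the matrix genes. Wnt targets were lower with 10 of 11 fold changes below 0, 5 past the test adjusted over the list alone and a median of -0.35 (camera adjusted p = 0.00112; adjusted p = 0.623 with an estimated correlation). The transcription factor MYC was at 125 ± 21.4 and 66.5 ± 12.2 FPKM (log2 fold change -0.90 ± 0.17, SE), cyclin D1 (CCND1) at 23.4 ± 0.988 and 16.1 ± 0.663 FPKM, BMP4 at 7.98 ± 0.0495 and 5.80 ± 0.190 FPKM, and ZNRF3 at 7.09 ± 0.347 and 4.96 ± 0.510 FPKM. YAP and TAZ targets were lower with 8 of 12 fold changes below 0, 4 past the test adjusted over the list alone and a median of -0.17 (camera adjusted p = 0.0478; adjusted p = 0.623 with an estimated correlation). TEAD4 was at 18.5 ± 2.45 and 12.8 ± 0.708 FPKM, ARHGEF17 at 3.58 ± 0.320 and 2.46 ± 0.0939 FPKM, FJX1 at 16.7 ± 2.36 and 12.02 ± 1.26 FPKM, and WWC1 at 9.16 ± 1.07 and 6.87 ± 0.347 FPKM. The list mean was 2.87 in PBS-1, 2.82 in PBS-2, 2.67 in PBS-3, 2.55 in oxamate-1, 2.70 in oxamate-2 and 2.56 in oxamate-3, so it was highest in the 3 libraries with the higher interferon means, and with the interferon list mean as a covariate its adjusted p was 0.260. This last list lost its call with no filter (adjusted p = 0.0515), with quantile normalization (0.0569) and without any of PBS-1, PBS-2, oxamate-1 or oxamate-3, at adjusted p-values of 0.0682, 0.206, 0.0804 and 0.0873.

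Amino acid response genes driven by ATF4 were lower, with 29 of 34 fold changes below 0, 0 past the test adjusted over the list alone and a median of -0.39 (camera adjusted p = 0.00252; adjusted p = 0.783 with an estimated correlation). The amino acid transporter SLC7A5 was at 100.3 ± 10.9 FPKM with PBS and 60.04 ± 20.0 FPKM with oxamate, the pseudokinase TRIB3 at 15.6 ± 2.89 and 9.56 ± 2.44 FPKM, CEBPB at 7.38 ± 1.83 and 4.00 ± 1.03 FPKM, and CBS at 22.3 ± 1.48 and 16.2 ± 3.68 FPKM. The list mean was 4.96 in PBS-1, 4.83 in PBS-2, 4.62 in PBS-3, 4.18 in oxamate-1, 4.99 in oxamate-2 and 4.19 in oxamate-3. The list lost its call without PBS-2 (adjusted p = 0.0648).

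Fatty acid synthesis and the pentose phosphate pathway were lower. Of 14 genes of fatty acid synthesis 12 had a fold change below 0, 2 passed adjusted over the list alone and the median was -0.21 (camera adjusted p = 0.0212; adjusted p = 0.623 with an estimated correlation). The fatty acid synthase FASN was at 197 ± 16.2 FPKM with PBS and 142 ± 11.7 FPKM with oxamate, SCD5 at 5.17 ± 0.280 and 3.32 ± 0.552 FPKM, FADS2 at 10.05 ± 0.570 and 8.18 ± 0.750 FPKM, and ACLY at 172 ± 5.59 and 149 ± 4.49 FPKM. Of 10 genes of the pentose phosphate pathway 9 had a fold change below 0, 3 passed adjusted over the list alone and the median was -0.14 (camera adjusted p = 0.0281; adjusted p = 0.623 with an estimated correlation). PRPS2 was at 37.3 ± 2.87 and 25.6 ± 1.23 FPKM, the transketolase TKT at 203 ± 15.1 and 155 ± 2.03 FPKM, and H6PD at 5.43 ± 0.370 and 4.21 ± 0.866 FPKM. The first of these lists lost its call without PBS-2 (adjusted p = 0.106), and the second without PBS-1 (0.0682), PBS-3 (0.0767) or oxamate-3 (0.0512).

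NF-kappa B targets were lower with 8 of 9 fold changes below 0 and a median of -0.72 (camera adjusted p = 0.0472; adjusted p = 0.767 with an estimated correlation). BCL3, which passed adjusted over the list alone, was at 5.29 ± 1.78 FPKM with PBS and 2.22 ± 0.234 FPKM with oxamate. NFKB2 was at 28.98 ± 10.9 and 16.7 ± 7.44 FPKM, RELB at 8.68 ± 3.66 and 4.33 ± 3.42 FPKM, and IRF1 at 4.51 ± 1.11 and 2.95 ± 1.05 FPKM. The list mean was 4.05 in PBS-1, 3.63 in PBS-2, 3.24 in PBS-3, 2.83 in oxamate-1, 3.63 in oxamate-2 and 2.84 in oxamate-3, so it was highest in the 3 libraries with the higher interferon means. Epithelial markers were lower in 5 of 5 tested genes with a median of -0.59 (camera adjusted p = 0.0478; adjusted p = 0.690 with an estimated correlation), with 1, CDH1, past the test adjusted over the list alone. KRT8 was at 80.03 ± 19.99 and 54.0 ± 21.0 FPKM, EPCAM at 1.58 ± 0.669 and 1.01 ± 0.251 FPKM, and KRT17 at 6.24 ± 5.67 and 1.09 ± 1.51 FPKM. KRT17 stood at 11.5, 7.01 and 0.228 FPKM in PBS-1, PBS-2 and PBS-3 and at 0.297, 2.83 and 0.141 FPKM in oxamate-1, oxamate-2 and oxamate-3, and the interferon list had its higher means in the same 3 libraries. Both lists lost their call without PBS-1, PBS-2, oxamate-1 or oxamate-3, at adjusted p-values from 0.0804 to 0.206. Epithelial markers also lost theirs with pseudocounts of 0.1 (0.0539) and 0.5 (0.0515) and with no filter (0.0529), and NF-kappa B targets with a minimum of 5 FPKM (0.213).

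**Figure D2:**
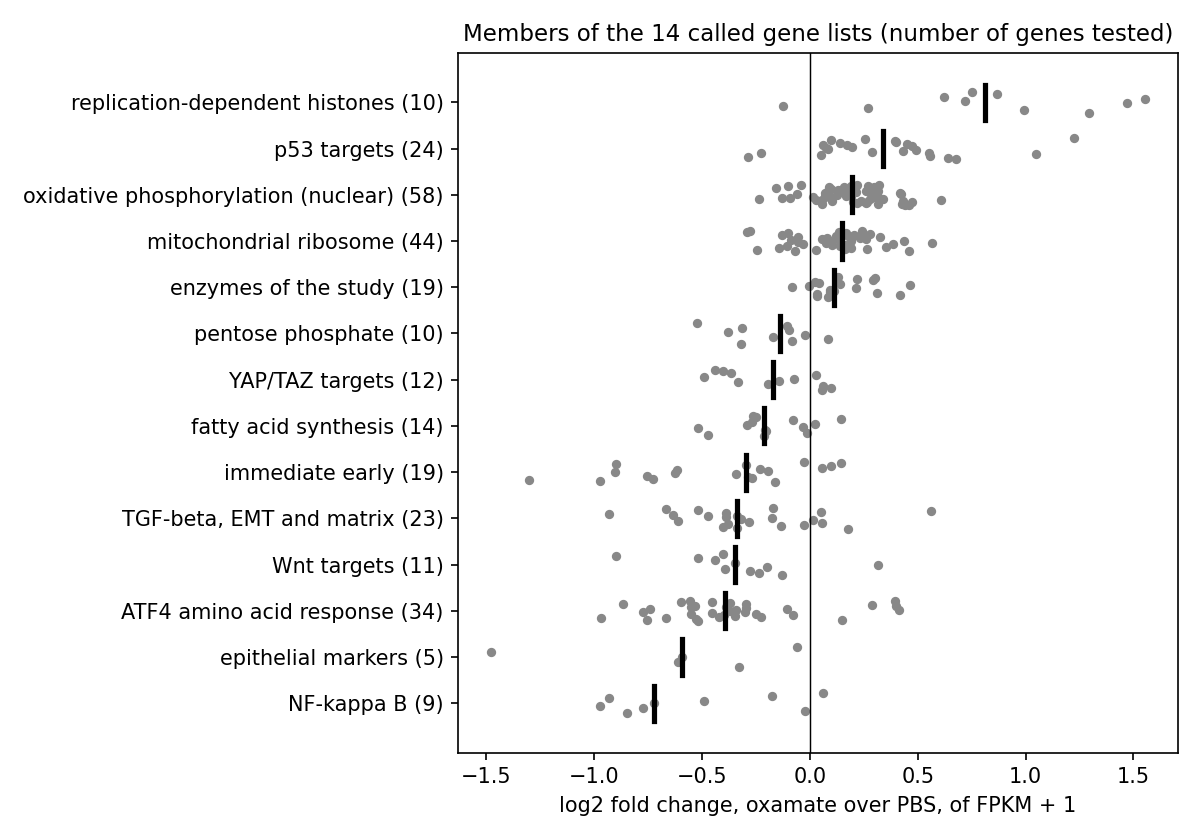
Log2 fold change (horizontal axis, oxamate over PBS, of FPKM + 1) of each tested member (grey points) of the 14 lists called by camera, with the list's median as a black bar and the number of genes in brackets. Medians run from -0.72 for NF-kappa B targets to 0.81 for replication-dependent histones.

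The remaining metabolic and growth lists were not called. Of 26 glycolysis genes 15 had a fold change below 0, with a median of -0.08 (camera adjusted p = 0.198), and PFKP passed adjusted over the list alone. The glycolysis list was called lower with quantile normalization (adjusted p = 0.0335) and with the interferon list mean as a covariate, chosen after the data were seen (0.0255), and in no other fit. Targets of hypoxia-inducible factors had a median of -0.12 over 24 genes (camera adjusted p = 0.198), the tricarboxylic acid cycle 0.04 over 23 genes (0.848), cholesterol synthesis -0.03 over 25 genes (0.699) and ribosomal proteins 0.11 over 58 genes (0.102). Cell cycle genes of the G1/S transition had a median of -0.01 over 42 genes (0.855), and those of mitosis 0.10 over 40 genes (0.0515). Histone acetyltransferases had a median of 0.02 over 24 genes (0.855) and deacylases -0.08 over 17 genes (0.886). The interferon list had a median of -1.26 over 17 genes and was not called (0.173).

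Among the authors' deposited results, 5 genes had a false discovery rate under 0.05. These were LINGO1, GYLTL1B and TP53I11 among the lower genes and DAXX and LINC01004 among the higher ones. The 3 lower genes were also called in limma. LINC01004 had an adjusted p of 0.0602 in limma, at 0.718 ± 0.0311 FPKM with PBS and 1.65 ± 0.0364 FPKM with oxamate. DAXX, a histone H3.3 chaperone on chromosome 6, lay under the minimum of 1 FPKM, at 0.112 ± 0.0137 and 0.899 ± 0.325 FPKM, and the listed genes of the major histocompatibility complex region around it had a median of 0.532 FPKM against 9.82 FPKM for protein-coding genes elsewhere. Among the authors' deposited results, 1166 genes had a false discovery rate under 0.10 and 3088 an unadjusted p under 0.05.

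The libraries also differed in ways that did not follow the groups. Fold changes fell with the GC content of transcripts, with a Spearman rho of -0.425 across 12305 genes, which are not independent replicates. The slope on GC content was taken of each gene's deviation from its mean over the 6 libraries, so it is relative to that average. In log2 units per 10 percentage points, it was 0.11 in PBS-1, -0.11 in PBS-2, 0.19 in PBS-3, -0.06 in oxamate-1, -0.12 in oxamate-2 and -0.01 in oxamate-3. With a correction for this slope, chosen after the data were seen, 86 genes were higher and 148 lower in limma, all 4 genes above were again called, and 10 of the 14 lists were again called in the same direction. The lists that were not called again kept their direction. Their corrected medians were -0.14 for the pentose phosphate pathway (adjusted p = 0.118), -0.12 for YAP and TAZ targets (0.128), -0.58 for NF-kappa B targets (0.118) and -0.51 for epithelial markers (0.112), against -0.14, -0.17, -0.72 and -0.59 without the correction. With the mean of the interferon list as a covariate, 0 genes were called in limma, 3216 had an unadjusted p under 0.05, and 5 of the 14 lists were again called in the same direction, namely nuclear oxidative phosphorylation, replication-dependent histones, immediate-early genes, matrix genes and Wnt targets. The others had adjusted p-values from 0.0553 to 0.260, with ATF4 targets at 0.129 and the study's enzymes at 0.0814.

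**Figure D3:**
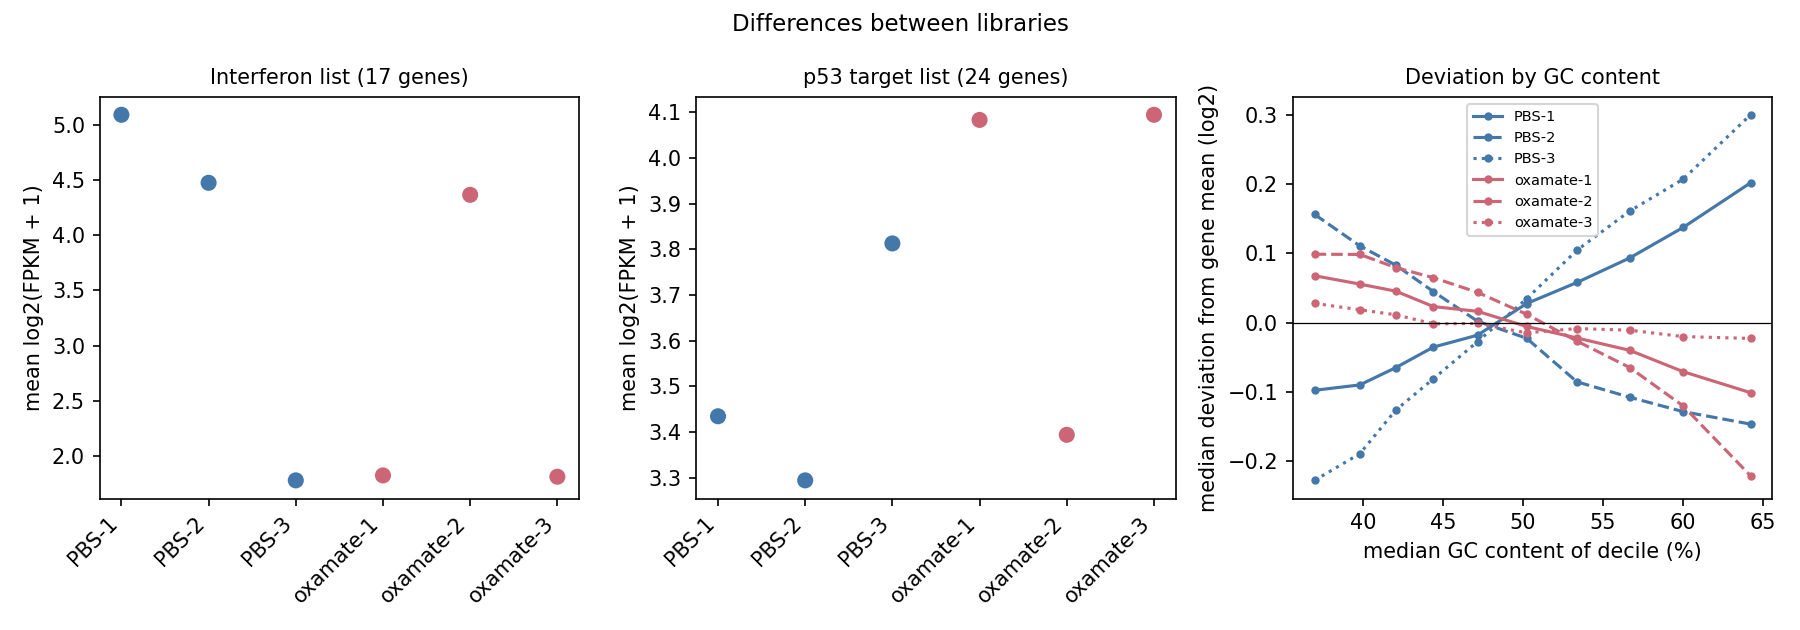
Left and middle: mean log2(FPKM + 1) of the interferon list and of the p53 target list in each library, with PBS in blue and oxamate in red. Right: median deviation of genes from their mean over the 6 libraries (log2) by decile of transcript GC content (%). The interferon means lie at 5.09, 4.48 and 4.37 in PBS-1, PBS-2 and oxamate-2 and between 1.78 and 1.82 in the other 3 libraries, and the GC slopes of PBS-1 and PBS-3 rise while those of the other 4 libraries fall.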

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

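The calls per gene were few and moved with the libraries used. Every result below is set against 1 higher and 3 lower genes, a share of 25% higher, 5 higher and 9 lower lists, and 3 genes shared with the authors' calls. Pseudocounts of 0.1 and 0.5, no filter, a minimum of 5 FPKM, median-of-ratios scaling, and a robust prior left the same 4 genes called, quantile normalization called these and 1 more, and limma without a trend called 3 of them. Leaving out single libraries gave 0 to 827 higher genes, 0 to 1273 lower genes, 2 to 7 higher lists, 4 to 11 lower lists and 0 to 4 genes shared with the authors' calls. The upper counts of genes came without PBS-2, where the share of higher calls was 39.4%, and each other omission left 0 calls. Without PBS-2 the GC slopes of the remaining libraries separated by group, so these upper counts cannot be told apart from a GC bias. An adjusted p under 0.01 left 0 higher and 0 lower genes and 0 shared with the authors, with 2782 genes at an unadjusted p under 0.05 in limma.

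Whether the replicate numbers pair the samples stays open, as the labels do not say. Same-numbered libraries had deviations from their group means that correlated at -0.33, 0.34 and 0.50, and not every library correlated best with its own number. Deviations within a group are not independent of each other, so these correlations cannot decide it. With the replicate number as a block, limma called 50 higher and 182 lower genes. Under the block the pentose phosphate list (adjusted p = 0.0507) and YAP and TAZ targets (0.0615) lost their calls, and interferon genes, lower, and mitosis, higher, were called at 0.0478 each.

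The alternatives added after seeing the data moved counts further. The GC correction gave 86 higher and 148 lower genes, a share of 36.8% higher and 5 lower lists. The GC correction with the replicate block gave 7 higher and 4 lower genes, a share of 63.6% and 2 genes shared with the authors. It called 3 of the 4 genes again and not GYLTL1B (adjusted p = 0.0602). The interferon covariate gave 0 higher and 0 lower genes, 5 lower lists and 0 genes shared with the authors. Averaging oxamate replicates 1 and 3 gave 0 higher and 0 lower genes and 0 shared, with 1806 genes at an unadjusted p under 0.05, in a fit with 1 sample fewer. RefSeq protein-coding genes alone gave 0 higher genes and a share of 0%, since SNORA72 is not protein-coding. This filter also ended the calls of YAP and TAZ targets (adjusted p = 0.0514), NF-kappa B targets (0.0511) and epithelial markers (0.0514), and called mitosis (0.0354) and metallothioneins and zinc transport (0.0491) higher. An adjusted p under 0.10 gave 326 higher and 606 lower genes. An estimated correlation left 0 higher and 0 lower lists, and so did fry. Apart from the SNORA72 call with protein-coding genes alone, the averaging and the changed thresholds, the cause was not tested.

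Over all alternatives, no gene or list called with the reported settings was called in the other direction. The list for stress of the endoplasmic reticulum, not called with them, was called lower without oxamate-2 (adjusted p = 0.00121) and higher with the interferon covariate (0.0217). Named genes and lists kept their side of the threshold in 1671 and 926 comparisons, lost a call in 35 and 79, and gained one in 118 and 27. Only the 4 called genes and 14 called lists had a call to lose. Most comparisons that kept their side were of genes and lists that were not called, so these counts do not measure how stable the calls were. Lists called only under an alternative included glycolysis, lower with quantile normalization (adjusted p = 0.0335), interferon genes, lower without PBS-3 (0.000449) or oxamate-2 (0.00281), and mitosis, higher without PBS-2 (0.00293), oxamate-1 (0.0426) or oxamate-3 (0.0487). Besides those under the protein-coding filter, calls lost to the expression filter, pseudocount or scaling were those of YAP and TAZ targets with no filter (0.0515) and quantile normalization (0.0569), of epithelial markers with no filter (0.0529) and pseudocounts of 0.1 (0.0539) and 0.5 (0.0515), and of NF-kappa B targets with a minimum of 5 FPKM (0.213). Metallothioneins and zinc transport were called higher without PBS-1 (0.0401), oxamate-1 (0.0426) or oxamate-3 (0.0380), and renal development lower without PBS-1 (0.0321) or oxamate-1 (0.0426). Ribosomal proteins were called higher without PBS-1 (0.00744), PBS-3 (0.000449) or oxamate-3 (0.0380), all fits that kept PBS-2, where this list had its lowest mean. Count-based fits with edgeR or DESeq2 and a protein-coding filter from the file's own gene types were not run, because the table used here gives neither counts nor gene types. Depth limits short genes and genes near 1 FPKM most. At 1 FPKM a gene of median length had a counting error of 16.98% in the shallowest library.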

Other observations

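The tests of GC slopes, of interferon means, of markers and of the major histocompatibility complex region were chosen after their values were seen, and the genes named in the next paragraph were chosen after their values were seen. The test of exchanged labels, the count of lists after the GC correction and the splits of the libraries were set before their results were seen. The use of Pearson's r beside Spearman's rho in the test of exchanged labels was set after its result was seen. The criterion for low transcription was reworded after a first form failed on RPS9, and the marker test was set to stay open unless 0.5 of each list was measured.

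Some lists that were not called as a whole held members past the test adjusted over the list alone. Of 7 genes of metallothioneins and zinc transport, 3 were higher and 1 lower by that count (camera adjusted p = 0.0540 for the list). The metallothionein MT1X was at 16.7 ± 1.69 FPKM (SD, n = 3) with PBS and 33.4 ± 6.15 FPKM with oxamate, MT2A at 21.6 ± 4.30 and 33.0 ± 2.57 FPKM, the zinc exporter SLC30A1 at 6.11 ± 0.142 and 8.99 ± 1.43 FPKM, and the zinc importer SLC39A10 at 20.1 ± 3.55 and 14.2 ± 1.87 FPKM. Of 11 genes of acid and carboxylate transport, 2 were higher and 4 lower. The carbonic anhydrase CA2 was at 216 ± 9.15 and 133 ± 17.5 FPKM, and the monocarboxylate transporter SLC16A4 at 1.37 ± 0.107 and 2.60 ± 0.160 FPKM. Of 9 neuronal genes, 5 were lower and 1 higher, with the neurofilament NEFM at 24.6 ± 5.61 and 11.7 ± 2.395 FPKM and the related INA at 3.68 ± 0.664 and 6.09 ± 1.12 FPKM. The phosphofructokinase PFKP was at 46.5 ± 7.03 and 27.1 ± 1.19 FPKM, the mitochondrial isocitrate dehydrogenase IDH2 at 56.3 ± 8.42 and 34.6 ± 1.53 FPKM, and the carnitine acetyltransferase CRAT at 15.3 ± 2.34 and 8.28 ± 0.728 FPKM. None of these genes passed over all genes tested in limma.

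With 10 splits of the 6 libraries into 3 and 3, no share under 0.05 can be reached. The labelled split called 4 genes and the highest other split called 77, so 2 of the 10 splits had as many. That other split set PBS-1, PBS-2 and oxamate-2 against the rest, and it points to a structure of the samples that the labels do not name. For the lists, the labelled split called 14 and the highest other split, the same one, called 16, and again 2 of 10 splits had as many. Every remaining split also called lists, 6 or more each, so list calls at the preset correlation did not need the labelled groups. At an unadjusted p under 0.05 in limma the labelled split had 2782 genes and the split of PBS-1, PBS-2 and oxamate-2 against the rest had 1435.

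That structure is led by interferon-stimulated genes. Of 20 measured members of the interferon list, 16 were higher in each of PBS-1, PBS-2 and oxamate-2 than in any of the other 3 libraries. IFIT1 was at 264, 173 and 1.81 FPKM in PBS-1, PBS-2 and PBS-3 and at 2.01, 117 and 2.18 FPKM in oxamate-1, oxamate-2 and oxamate-3. If the labels of PBS-3 and oxamate-2 had been exchanged, the difference between them should run against that between the other 4 libraries. After GC correction and without the interferon and NF-kappa B lists, the Spearman rho of the 2 differences was 0.148 across 12279 genes and Pearson's r was 0.02, while the other 8 pairs gave a rho of 0.461 to 0.605. The first lay above the bound of 0.1 set against an exchange and the second below it. With single libraries there is no spread to judge either by, so an exchange of these labels stays open. Another cell type in 3 cultures stays open: in the fixed lists of haematopoietic, epithelial and fibroblast or endothelial markers, 0 markers were over 5 FPKM in these 3 libraries and under 1 FPKM in the others, but only 2, 6 and 5 of 12 markers each were among the rows used here. CD68 stood between 1.38 and 2.81 FPKM, COL1A1 between 4.23 and 7.83 FPKM and KRT18 between 59.0 and 75.5 FPKM, and none of these set the 3 libraries apart. Other markers did: in PBS-1, PBS-2 and oxamate-2 KRT8 was at 98.4, 82.9 and 78.2 FPKM, KRT17 at 11.5, 7.01 and 2.83, EPCAM at 2.13, 1.78 and 1.27 and LUM at 2.07, 1.97 and 1.59. In PBS-3, oxamate-1 and oxamate-3 KRT8 was at 58.8, 42.4 and 41.3 FPKM, KRT17 at 0.228, 0.297 and 0.141, EPCAM at 0.835, 0.771 and 0.993 and LUM at 1.15, 0.700 and 0.596. A response to oxamate cannot be told apart from chance at this size, since the groups overlap and the exact two-sided permutation p of the interferon means was 0.4 where 0.1 is the smallest possible. A state of the cultures such as exposure to nucleic acid was not tested.

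The fall of fold changes with GC content may come from the libraries. The slopes within PBS spanned 2.41 times the difference between the group means, so a GC bias between libraries has the values it needs. A response to oxamate cannot be told apart from it with 3 libraries a group, as the exact two-sided permutation p of the slopes was 0.3. GC bias as the whole cause of the list calls is argued against by the correction, under which 10 of 14 called lists stayed past the threshold in the same direction, where fewer than 7 had been required. The other 4 lists lost their call but kept their direction, with medians from -0.58 to -0.12 after the correction and from -0.72 to -0.14 before it.

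Many genes of the major histocompatibility complex region on chromosome 6 were listed near 0, though not all: TUBB, in this region, was at 15.2 FPKM. Of 167 annotated protein-coding genes 53 were listed (31.7%), against 64.6% elsewhere. RPS18, a ribosomal protein gene of this region, was at 1.89 FPKM, or 0.219% of the median of 58 ribosomal protein genes (861 FPKM), and the region's median was 5.42% of that elsewhere. For RPS18, low transcription in these cells is argued against, since 96.5% of the other 57 ribosomal protein genes lay above 0.1 of that median and the ribosome needs each protein. For the region's other genes it stays open. A candidate explanation is that fragments were lost at genes with near-identical copies on the alternate sequences that hg38 carries for this region. RPS9, at 1.47 FPKM, lies on chromosome 19 in a region that also has such sequences. RPS28, at 21.96 FPKM elsewhere on chromosome 19, was the other ribosomal protein gene under 0.1 of the median. DDT, on chromosome 22, was at 33.6 FPKM in oxamate-2 and between 0.160 and 0.628 FPKM in the other 5 libraries. TUBB, RPS9, RPS28 and DDT were chosen after their values were seen, and the alignments themselves were not examined. DAXX, called in the authors' deposited table, lies in this region at 33318558 to 33322959 and was at 0.0987, 0.111 and 0.126 FPKM in PBS-1, PBS-2 and PBS-3 and at 0.930, 0.560 and 1.21 FPKM in oxamate-1, oxamate-2 and oxamate-3. Whether its difference reflects its transcript level stays open.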
